A study of Conopomorpha sinensis with 2 samples.

How the data were processed

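Poly(A)-selected RNA from larvae of instar 5 was sequenced on an Illumina HiSeq instrument in 2 libraries, 1 labelled no-pesticide and 1 labelled pesticide. Groups were taken from the background label of each sample. The labels do not say how many larvae went into each library, and the name of the pesticide is not given in the sources used here.

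The authors deposited 1 table per library with 2 measurements per unigene. The first is an estimated count of reads per unigene, not normalized, per the file headers and the values. It is not a whole number for 20.3% of entries in the no-pesticide library and 20.7% in the pesticide library. The second is FPKM, which the authors scaled by unigene length and by the library's reads, per the file headers. CASAVA 1.8 and RSEM, which divides reads shared between transcripts in proportion to estimated abundance, are named in the submitters' processing notes. The RSEM version, the aligner, the way the unigenes were obtained, the strand setting and any filters are not given in the sources used here. The IDs have a component number and a sub-number, and 702 of the 35383 unigenes were at 0 in both libraries. Counts of unigenes with near-identical copies are uncertain, since such reads are split by estimation, and these unigenes could not be identified without sequences.

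Estimated counts were rounded to whole numbers, which gave 25174381 reads in the no-pesticide library and 21089891 in the pesticide library. A count of 3, used as the floor for a value of 0, equals 0.119 and 0.142 CPM (counts scaled to a library size of 1000000) in these libraries. Library sizes were scaled by the TMM factors of edgeR 4.0.16 in R 4.3.3, computed over unigenes with a summed count of at least 20. The factors were 0.887 for the no-pesticide library and 1.13 for the pesticide library, a shift of -0.35 on the log2 scale in the ratio against total counts. These unigenes held 99.8% of the no-pesticide and 99.7% of the pesticide reads.

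The design has no replicates, so no test of the pesticide label and no p-value was computed. For each unigene the ratio of scaled counts, pesticide over no-pesticide, was given with an exact 95% interval from the conditional binomial distribution (Clopper-Pearson, scipy 1.17.1). A unigene was counted as higher or lower when its whole interval lay above 2 or below 0.5. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Log2 ratios used a prior count of 0.5. The spread of the ratios was the median absolute log2 ratio over unigenes with at least 100 summed reads, set beside binomial resampling at equal expression. Its interval came from 300 bootstrap draws over unigenes. Correlations were computed on log2(FPKM + 1).

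Choices of groups, bounds, filters, alternatives and named unigenes were fixed before the data were examined, except where the text says otherwise. The rule for named unigenes ranked all tested unigenes by the interval bound nearest 1 and took the 2 highest and the 2 lowest, the limit set for IDs without gene names. Lists of detoxification, insecticide target, stress, cuticle, digestive, immune and tissue genes had also been fixed, but were not evaluated because no ID could be matched to a gene name.

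The ratio counts were tested on simulated libraries drawn from the observed mean abundances, with 200 unigenes changed by known folds. Of the changed unigenes that reached the count minimum, 0 of 48 with a true fold of 1.5 passed the 2-fold bound. The bound was passed by 34 of 50 (68%) at a true fold of 3, by 39 of 49 (79.6%) at 4 and by 47 of 47 at 8. No changed unigene passed on the wrong side, and 0 of 17253 unchanged unigenes passed. With counting error alone, a whole interval beyond the 2-fold bound is very rare without a change, so this result was nearly certain beforehand. Apart from the changed unigenes, both libraries were drawn from the same mean abundances. The simulation therefore could not check the choice of scaling. Further simulations without changed unigenes added a biological coefficient of variation of 0.1, 0.2 or 0.4 per library.

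Alternatives were DESeq2 1.42.0 median-of-ratios size factors, total-count scaling, the deposited FPKM, other count minimums, a stricter interval, assumed biological variation and a 4-fold bound. Leaving out replicates was not possible with 1 library per group.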

Results

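Messenger RNA was sequenced from larvae of the litchi fruit borer, Conopomorpha sinensis, a moth whose larvae bore into litchi fruit. Both samples were taken at instar 5. One library came from larvae labelled as having no pesticide background and 1 library from larvae labelled with a pesticide background. The labels used here name no compound, dose or exposure time, and do not say whether the larvae were exposed themselves or came from a treated population. The study asked which genes differed in expression between these 2 groups. Estimated read counts and FPKM values were given for 35383 entries with component-style IDs, called unigenes here. The files do not pair these IDs with gene names or sequences, so genes could not be assigned to functions or placed on a genome.

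The no-pesticide library held 25174383 estimated reads and the pesticide library 21089856. With 1 library per group, no difference below has a replicate check. The intervals given cover counting error in these libraries only, and they compare the libraries rather than the conditions.

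More unigenes were detected in the pesticide library, although it had fewer reads in total, and the size of the difference depended on how depth was matched. The pesticide library had reads in 32439 unigenes, against 32085 in the no-pesticide library, and 29843 unigenes had reads in both. Thinned to the total reads of the pesticide library, the no-pesticide library kept a mean of 31384 unigenes with at least 1 read (SD 31.1 over 20 random draws), compared with 32437 in the pesticide library. At least 10 reads were left in 16293 unigenes of the thinned no-pesticide library (SD 19.8) and were present in 17768 unigenes of the pesticide library. Matching total reads leaves more reads for the less abundant unigenes of the pesticide library, whose most abundant unigenes took a smaller share. Thinned instead to the TMM-scaled depth of the no-pesticide library, the pesticide library kept a mean of 32220 unigenes with at least 1 read (SD 16.4) and 17413 with at least 10 (SD 15.9), compared with 32084 and 17173 in the no-pesticide library. Both thinnings were added after the data had been seen.

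The most abundant unigenes took a smaller share of reads in the pesticide library. The 100 most abundant unigenes held 51.2% of reads in the no-pesticide library (exact binomial 95% interval 51.18 to 51.22%) and 46.2% in the pesticide library (46.15 to 46.19%). The 10 most abundant held 28.5% and 23.9%, respectively. The same unigene ranked first in both libraries, with 7.02% of the no-pesticide reads and 5.78% of the pesticide reads. Its deposited FPKM was 45944 in the no-pesticide library and 37679 in the pesticide library. Of the 100 most abundant unigenes in each library, 81 were common to both lists.

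**Figure D1:**
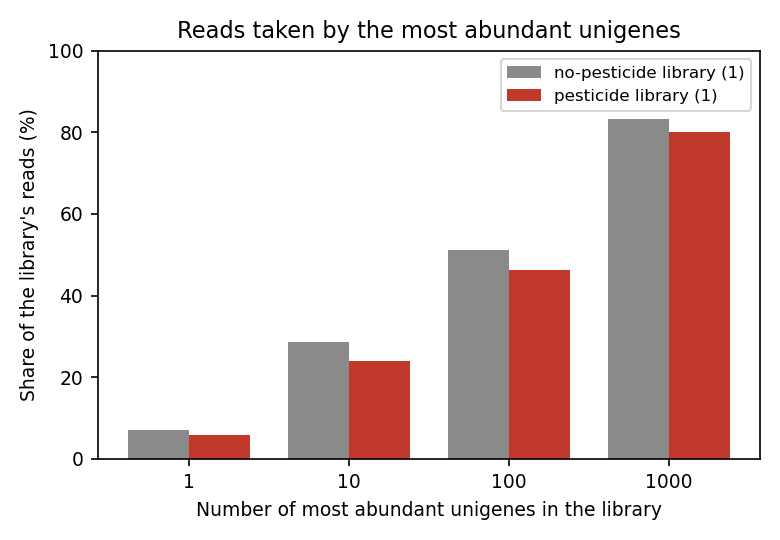
Share of each library's reads (vertical axis, percent) taken by its 1, 10, 100 and 1000 most abundant unigenes (horizontal axis), with 1 bar per library. The no-pesticide bar is the higher one at each number, for example 83.3% against 80.0% for the 1000 most abundant.

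Differences in individual unigenes went in both directions. Of 17409 unigenes with at least 20 reads over both libraries, 558 (3.21%) were higher in the pesticide library, with the whole 95% interval of the ratio of TMM-scaled counts above 2. Another 706 (4.06%) were lower, with the whole interval below 0.5. At a bound of 4-fold, 106 were higher and 173 lower, and at 16-fold 12 were higher and 13 lower. For 8789 unigenes (50.5%) the interval included a ratio of 1. The remaining 7356 had an interval that excluded 1 but did not lie wholly beyond the 2-fold bound. These intervals were not adjusted for the number of unigenes, so counting error alone would make some of them exclude 1. Whether an interval includes 1 also depends on the scaling.

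The balance of directions followed the scaling of the libraries. Scaled to total counts, 1095 unigenes were higher and 400 lower, so that 73.2% of the unigenes beyond 2-fold were higher in the pesticide library, compared with 44.1% under TMM. The deposited FPKM values, which are also relative to total reads, gave 1158 higher and 407 lower. The median log2 ratio of the tested unigenes was 0.36 with total-count scaling and 0.01 with TMM. Ratios below are given relative to the TMM scale.

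**Figure D2:**
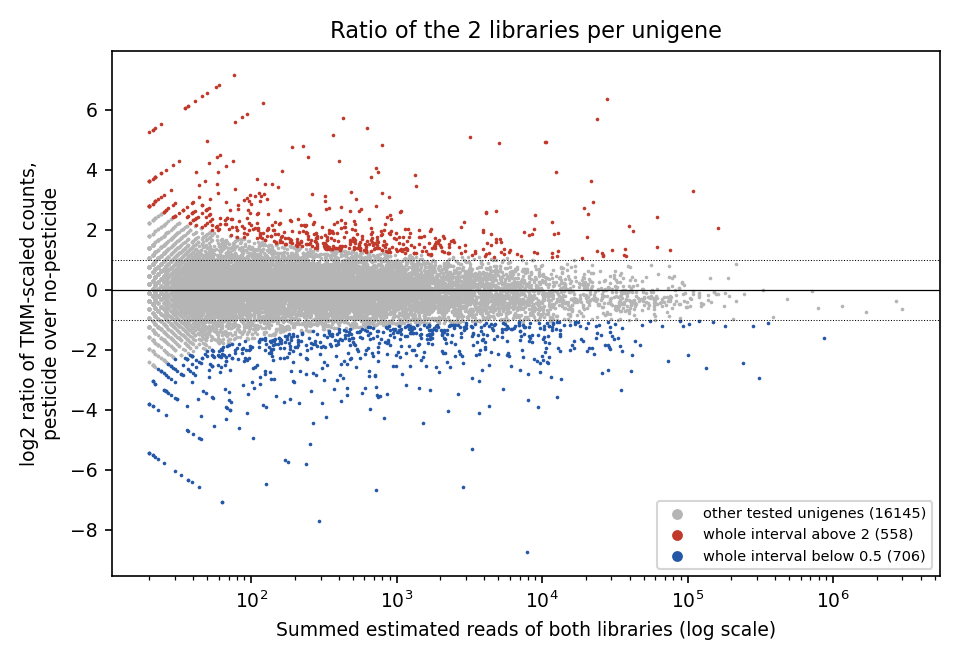
Log2 ratio of TMM-scaled counts, pesticide over no-pesticide (vertical axis), against the summed reads of both libraries (horizontal axis, log scale), with 1 point per unigene of at least 20 summed reads. Red points (558) have their whole 95% counting interval above 2 and blue points (706) below 0.5, the dotted lines mark the 2-fold bounds, and 0.5 was added to each count before taking the log.

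The 2 unigenes furthest above 1 after allowing for counting error belonged to the abundant unigenes of the pesticide library. comp47065_c0 had 314 reads in the no-pesticide library and 27659 in the pesticide library, a ratio of 82.7 (95% counting interval 73.96 to 92.68). Its FPKM went from 16.88 to 1787.58, and it ranked 105 by read count in the pesticide library and 4431 in the no-pesticide library. comp51574_c0 had 426 and 23304 reads, a ratio of 51.3 (46.6 to 56.6), with FPKM values of 29.30 and 1929.53, and ranked 136 in the pesticide library.

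In the other direction, comp49018_c0 ranked 450 in the no-pesticide library with 7874 reads and had 19 reads in the pesticide library. It was 442-fold lower there (283 to 734), with FPKM values of 299.38 and 0.87. comp52389_c0 had 2838 and 31 reads and was 97.6-fold lower (68.6 to 144). On total counts the same unigene was 76.7-fold lower, and on the deposited FPKM values (232.75 and 4.32), which also take length into account, 53.9-fold lower. The length implied by its count and FPKM was 484 bases in the no-pesticide library and 340 bases in the pesticide library. The other 3 named unigenes had implied lengths that differed by less than 10 bases between the libraries.

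Among the 100 unigenes most abundant over both libraries, 5 were higher in the pesticide library beyond 2-fold and 15 were lower. Their median log2 ratio was -0.33. With total-count scaling 7 were higher and 6 lower, and the median was 0.01, so the direction for this group depended on the scaling. The most abundant unigene had a ratio of 0.648 on the TMM scale (0.647 to 0.650) and of 0.825 on total counts (0.823 to 0.826). Within this group the lowest ratio belonged to a unigene with 272778 reads in the no-pesticide library and 38225 in the pesticide library, which was 7.60-fold lower (7.52 to 7.69). The highest belonged to a unigene with 9596 and 99480 reads, which was 9.73-fold higher (9.53 to 9.94).

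Few unigenes above the count minimum were found in a single library. With at least 20 reads in one library and 0 in the other, 16 unigenes were detected only in the no-pesticide library and 15 only in the pesticide library. Their median counts were 27.5 and 37 reads, not far above that minimum. The best covered of them had 63 reads in the no-pesticide library and 76 reads in the pesticide library. Against a floor of 3 counts in the library without reads, these were at least 22.4-fold and at least 23.8-fold higher, respectively. The 95% interval used for the other ratios, which is two-sided, reached down to 17.7-fold and 18.9-fold for these unigenes.

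Over 10509 unigenes with at least 100 summed reads, the median absolute log2 ratio was 0.40 (bootstrap 95% interval 0.39 to 0.41), or 1.32-fold. Resampling of the same reads at equal expression gave 0.07, or 1.05-fold, which is the part of the spread that counting error alone would give and does not include the variation between separate samples. Across all 35383 unigenes, log2(FPKM + 1) values of the libraries correlated with Pearson's r = 0.878 and Spearman's rho = 0.654. These correlations are across genes, which are not independent replicates. They include the 702 unigenes at 0 in both libraries. The median count was 9 reads in the no-pesticide library and 10 in the pesticide library. Counting error and ties at such low counts can lower rho, by an amount that was not tested.

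How many of the 1264 unigenes beyond 2-fold would differ again between further libraries of each group cannot be read from 1 library per group. In simulated libraries with counting error alone, 0 of the 17253 unigenes left unchanged passed the bound in either direction. That was nearly certain at a 2-fold bound, and it is no check of the scaling, since the simulated libraries shared one composition apart from the changed unigenes. In further simulations without any changed unigene, an assumed biological coefficient of variation of 0.2 in each library let 36 of 17430 unigenes pass as higher and 32 as lower. One of 0.3, which matched the observed median absolute log2 ratio of unigenes with at least 1000 summed reads, gave a mean of 597 in both directions together over 20 draws, against the 1264 observed. With one of 0.4, above that matched value, 848 of 17303 passed as higher and 824 as lower.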

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

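The alternatives that fitted TMM without the 100 most abundant unigenes, rescaled the FPKM, kept 1 unigene per component or centred on unigenes of similar FPKM were chosen after seeing the data. Higher and lower counts (558 and 706) stayed within 1.5 times under these and under size factors (550 and 722), other count minimums and an assumed biological coefficient of variation of 0.1 (389 and 503). They became 1095 and 400 with total counts, 1158 and 407 with deposited FPKM, 88 and 131 with an assumed coefficient of variation of 0.4, and 106 and 173 with a 4-fold bound. An interval with an error of 0.1% left 330 higher and 483 lower. The change with total counts comes from one factor applied to every unigene, and rescaling the FPKM by the TMM factors gave 604 and 716. The median absolute log2 ratio was 0.486 with total counts and 0.415 at 1000 or more summed reads. Pearson's r was 0.709 with a pseudocount of 0.1 and 0.871 for unigenes with FPKM of at least 1 in either library, where rho was 0.637. That FPKM filter still admits unigenes of few reads. Shares of the 100 most abundant unigenes were 50.7% and 45.8% when ranked over both libraries, and 52.0% and 45.9% of summed FPKM, in the no-pesticide and pesticide library. Unigenes in 1 library only numbered 78 (no-pesticide) and 72 (pesticide) at 10 reads, and 27 and 30 when 1 read was allowed in the other. No paired analysis was possible because each group has 1 library, and leaving out a replicate was likewise not possible. Gene lists could not be evaluated under any scaling, because no ID had a gene name. Depth limits which ratios can pass: in the simulation with counting error alone, 68% of 3-fold and 79.6% of 4-fold changes were recovered.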

Other observations

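Tests of abundance, length and background, and those of implied lengths, were chosen after the result was seen, whereas the prediction for the shared spread was written before. The well-covered unigenes that lay furthest apart between the libraries had lower median implied lengths than other unigenes of similar summed reads. At equal summed reads a shorter unigene has a higher FPKM, so length and FPKM cannot be told apart here. Of 3388 unigenes with at least 1000 summed reads, 11 were over 8-fold higher in the pesticide library by their whole interval, with a median implied length of 644 bases (202 to 1233). Random lists of the same size matched on summed reads had a median of 1419 bases, and 0.57% of 10000 such lists were as short. The 15 unigenes over 8-fold lower had a median implied length of 541 bases (51.5 to 1637), shorter than in any of the 10000 matched lists. The median of those lists was 1601 bases. Implied lengths were computed from counts and FPKM and need not equal the lengths of the assembled unigenes. Ratios of unigenes that share a component number were also correlated. Over 652 such pairs with at least 100 reads each, Spearman's rho of the log2 ratios was 0.41 (bootstrap 95% interval 0.34 to 0.48). Over the 100 pairs with whole-number counts it was 0.40 (0.20 to 0.58). Pairs of one component can share a unigene but were resampled as if independent, so these intervals may be too narrow. Each pair was entered in both orders. Pairs from different components, matched on abundance or length, were not compared, so the part due to those traits is not known.

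A first pattern was the number of unigenes beyond counting error. The tested explanation was one spread shared by all unigenes between the libraries, with no unigene changed. A coefficient of variation of 0.3 per library matched the observed median absolute log2 ratio (0.41) of unigenes with at least 1000 reads, and 20 simulated draws then gave a mean of 597 unigenes beyond 2-fold, against 1264 observed. Beyond 8-fold the highest draw had 0, against 82 observed, which argues against one gamma-distributed spread of this size. A shared spread with heavier tails, or one that varies with read count, was not simulated and stays open. Which far ratios follow the pesticide label, and which reflect larger spread of particular unigenes between larvae, also remains open with 1 library per group.

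A second pattern was a median ratio that fell with abundance. On the TMM scale the median log2 ratio was 0.10 for unigenes with a mean FPKM of 1 to 2 (bootstrap 95% interval 0.06 to 0.13) and -0.39 at 300 or more (-0.43 to -0.34), where 23 unigenes were higher and 83 lower beyond 2-fold. The class difference does not depend on the scaling, since one factor per library shifts all classes alike. From the shortest to the longest length quartile, unigenes of middle counts exceeded those of high counts by 0.62, 0.47, 0.33 and 0.17 (0.10 to 0.26 for the last). These classes were of read count rather than FPKM, and length was not held fixed within a quartile. In implied length, which need not equal the assembled length, the shortest quartile spanned 22.6 to 405 bases and the longest 1422 to 23534 bases. The comparison therefore cannot decide whether length was the whole cause or a part that grows in shorter unigenes, and both stay open. Background reads spread evenly in the pesticide library were sized to give the whole excess of 0.49 at FPKM 1 to 2 over 300 or more. They would leave an excess of 0.05 at FPKM 10 to 30, whereas 0.38 was observed (0.33 to 0.43). This argues against such background as the whole cause, while a part from it stays open. Base composition, amplification during library preparation and the pesticide label itself may each contribute and were not tested.

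A further pattern was that the length implied by count and FPKM differed between the libraries. Compared were 9713 unigenes with implied lengths of at least 300 bases and with at least 100 summed reads. Of these, 83.9% (8145) differed by over 0.5 bases more than rounding of the deposited values allows, so rounding does not account for them. A different mean fragment length would give a common offset, which was 5.08 bases. From that offset 47.3% (4592) still differed by over 0.5 bases more than rounding allows. Fragment length may thus account for a part of the differences, but not for those 4592. The share of all compared unigenes that differed by over 10% was 15.6% at 100 to 300 reads, 18.1% at 300 to 1000, 12.3% at 1000 to 3000, 6.46% at 3000 to 10000 and 3.40% (20 of 588) at 10000 or more, a ratio of 0.218 between the ends. Among unigenes differing beyond the offset, the median relative difference was 6.51% (5.87 to 7.26) at 100 to 300 reads, 5.63% (5.09 to 6.15) at 300 to 1000 and 1.07% at 10000 or more, a selection made on the difference itself. Noise in the estimated mix of transcripts per unigene at limited depth may account for the lower values at high depth, but the share did not fall at each step and the number of transcripts per unigene was not used here, so that noise and a change of transcript mix, with the pesticide label or between larvae, cannot be told apart.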
